A study of Mus musculus with 4 samples.

How the data were processed

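The series held 4 arrays, 2 of liver and 2 of spleen, from male C57BL/6J mice that were 7 weeks old. Per the labels, 1 group of mice ate a purified low-nucleoprotein diet with 0.03% nucleic acids, here called control, and the other ate the same kind of diet with 1.2% of a nucleoprotein product, which brought nucleic acids to 0.5%. After 4 weeks the mice received lipopolysaccharide, a bacterial cell wall component that sets off systemic inflammation, at 10 mg/kg, and the organs were taken 6 h later. RNA was pooled by diet before labelling. The array titles number the pooled samples 1 and 2 within each organ, and the labels do not say whether these were the same pools labelled again or pools of different mice. They were taken as 1 pool per diet and organ, the more cautious reading, and if they were separate pools the SD would also hold variation between mice. The housing notes name a standard chow and the study design a purified diet, and the design was followed for what the control mice ate, so the 0.03% rests on it. The number of mice behind a pool was not given in the sources used here. No mice without lipopolysaccharide were analysed here, so only the effect of diet in injected mice could be measured.

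Each array carried both pools of its organ, 1 in Cy3 (green) and 1 in Cy5 (red). On the replicate 1 arrays the nucleoprotein pool was in Cy5, and on the replicate 2 arrays it was in Cy3. The 2 arrays of an organ were treated as a technical dye swap and counted as 1 replicate, on the assumption above. All 4 arrays came from a single slide, so slide could not be separated from anything else. The SD printed beside a ratio is that of the 2 arrays and is taken to cover labelling and array error only. As the 2 arrays had opposite dye orientations, it also holds any gene-specific dye effect, which the mean of both balances.

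The deposited scanner files were made with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes, while the step version in the file headers was 9.5.1.1. Per the file headers, they gave for each spot the mean intensity and local background intensity in both channels, processed intensities after background subtraction and dye normalization, the log10 of red over green processed intensity, and a p-value of that log ratio from an error model within the array. The authors' series value table was set against the processed intensities of the same arrays. Its size was the linear ratio of red over green, within 0.02 log2 units for 99.85%, 100%, 99.98% and 99.92% of spots well above background in both channels on liver replicates 1 and 2 and spleen replicates 1 and 2. Every value of the replicate 1 arrays carried a minus sign in that table. Its column medians were -0.92, 0.92, -0.96 and 0.96, and it was not centred further. The ratio's scale and direction were thus known, and the purpose of the minus sign was not.

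Each array had 45018 spots, of which 43379 were gene spots for 41174 probes and 1639 were controls. Background was corrected with the normexp method at an offset of 50 (limma 3.58.1 in R 4.3.3), and the log2 ratio of red over green was normalized within each array by loess with control spots given no weight. Spots that Feature Extraction called non-uniform or population outliers were left out (between 189 and 354 gene spots per array). Saturated spots were to be kept, and there were 0. Spots of the same probe were averaged, and every ratio was turned to nucleoprotein over control. Levels of single channels came from the same values after Aquantile scaling between arrays. The precision of these arrays was limited by their number.

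Probes were named through a RefSeq gene table of assembly GRCm38.p6, used for names only. By accession 23082 probes matched, by name or synonym a further 9655, and 8437 kept the name in the file. This gave 27666 genes, of which 8923 had more than 1 probe. A gene was represented by its probe with the highest mean intensity over the 4 arrays. No probe of a gene named here had a change past the 1.5-fold bound on both arrays in the direction opposite to that of the representing probe (0 genes). Probe positions are those in the files, on mouse build mm7 (NCBI 35).

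A gene was measurable in an organ when its probe was well above background, on both arrays, in the channel of at least 1 diet. It was called higher or lower when its log2 ratio passed 1.5-fold (0.58 on the log2 scale) in the same direction on both arrays. With 1 pool per diet assumed there was no replicate check of a diet difference, no test was run and no p-value is given. As a measure of noise, genes past the same bounds in opposite directions on the 2 arrays were counted. Where a probe was not well above background in 1 diet on both arrays, the fold is given as a bound. The bright pool was set against the higher of the lowest signal among probes well above background and the dim probe's own, per array and channel.

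Before the data were examined, 42 gene lists (1238 entries, 1204 found on the array) were fixed for pathways and cell types. For each list the median log2 ratio of its measurable members was set against 10000 random lists of the same size matched on mean intensity in 20 bins. A list was called when its percentile was below 2.5 or above 97.5 and its median had the same sign on both arrays. The percentile describes these pools and is not a test across mice. Over 84 list medians, 4.2 would pass the percentile bounds by chance if genes were independent.

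The genes named were chosen by a rule fixed beforehand: per organ the 12 called genes with the largest rise and the 12 with the largest fall among those with official symbols; per list up to 4 called members, or its 2 brightest members where fewer than 2 were called; and up to 10 genes called in both organs. Genes outside the rule are named as chosen after their values were seen. The value of 1 gene that the rule names is not reported here.

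The procedure was tested on simulated arrays that kept the measured intensities, dye trends, dye bias per probe and spot noise. In the simulated liver comparison (16402 genes), 63 of 67 genes changed 2-fold, all 67 changed 3-fold and all 66 changed 4-fold were called. In the simulated spleen comparison (18139 genes), all 67, 67 and 66 were called. Unchanged genes gave 0 calls in either. A list made lower by 0.3 had a median of -0.31 in liver and -0.28 in spleen, and of 40 unchanged lists per organ 1 was called in liver and 0 in spleen. The simulated noise was that between spots of a probe on the same array, which leaves out labelling.

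The alternatives chosen beforehand were a normexp offset of 10, no background subtraction, median centring in place of loess, Feature Extraction's deposited log ratios, the authors' series value table, no filter or a stricter filter on background, outlier spots kept, saturated spots left out, the mean over all probes of a gene, a 2-fold bound, a deposited p-value below 0.01 on both arrays, the mean of both arrays alone, and each array alone. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.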

Results

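Gene expression was compared between mice fed a nucleoprotein diet and mice fed a control diet low in nucleoprotein, in liver and in spleen, 6 h after an injection of lipopolysaccharide. Each organ was measured on 2 two-colour arrays of opposite dye orientation, which carried the same 2 diets as pooled RNA. On the liver arrays 55.2% and 58.2% of gene spots were well above background in green and 66.9% and 66.5% in red. On the spleen arrays the shares were 62.2% and 66.8% in green and 71.6% and 72.8% in red. Ratios are log2 of nucleoprotein over control, as mean ± SD of the 2 arrays, and the 2 arrays of an organ were taken to hold the same pools, which the labels leave open.

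The arrays held the organs their labels name. Of 22 hepatocyte markers measurable in either organ, 22 were brighter on the liver arrays, by a median of 7.38 log2 units. All 21 B cell markers were brighter on the spleen arrays, with a median difference of -4.82 (liver minus spleen), as were 35 of 39 T cell and NK cell markers. The level of Alb, serum albumin, was 15.59 on the liver arrays and 8.92 on the spleen arrays, and that of the B cell surface gene Ms4a1 was 7.07 and 14.11.

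The first comparison asked which liver genes differed with nucleoprotein in the diet of injected mice. Genes of pancreatic acinar cells, which make digestive enzymes, made up the largest group. All 25 measured members of the acinar list were lower in the nucleoprotein pool, with a list median of -3.68 (-3.75 and -3.65 on the 2 arrays). Carboxypeptidase B1, Cpb1 (probe on chromosome 3, 19981484 to 19981543), was lower by -6.15 ± 0.25, or 71.2-fold. The elastase Cela3b was at -5.67 ± 0.15, the trypsinogen Prss3 at -5.59 ± 0.06, Reg1 at -5.29 ± 0.50, pancreatic lipase Pnlip at -4.79 ± 0.28 and pancreatic amylase Amy2 at -4.04 ± 0.18.

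The rest of the 12 largest falls in liver among genes with official symbols were acinar genes as well, namely Reg2 at -5.03 ± 0.58, the lipase-related Pnliprp1 at -4.60 ± 0.06, the trypsinogen Try5 at -4.28 ± 0.20, Cel at -4.15 ± 0.26, Cpa1 at -4.04 ± 0.12 and Sycn at -3.86 ± 0.02. The transcript 2210010C04Rik, called in both organs, was lower by -5.26 ± 0.41. In the nucleoprotein channel, Reg2 was well above background on 1 of the 2 arrays. Trypsinogens, amylases and elastases are families of similar sequence, so probes of 1 member can also bind others. In the nucleoprotein pool itself, 21 of the 25 list members were still well above background on both liver arrays.

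Outside that list 27 genes were lower in liver. These still held digestive enzyme genes missing from the list, such as the trypsinogens Prss3 and Try5 and the amylase Amy1. Among the fixed lists the 27 included Dbp, a clock-controlled transcription factor, at -1.47 ± 0.21. The inducible heat shock gene Hspa1a stood at -1.30 ± 0.14, and G6pdx, the entry enzyme of the pentose phosphate pathway, at -0.99 ± 0.25. Both Acss2, which makes acetyl-CoA from acetate, at -0.70 and -1.29 on the 2 arrays and Acly, which makes it from citrate, at -0.89 ± 0.04 were called within the fatty acid list. Chosen after their values were seen, further lower genes were the glandular kallikrein Klk1 at -1.31 ± 0.36, Dmbt1 at -2.01 ± 0.04, Arrdc3 at -0.93 ± 0.37 and Rgs16 at -0.69 ± 0.08. Other probes measured -0.32 for Klk1, -0.38 for Amy1 (against -3.00 for its representing probe) and -1.26 to -0.14 for Hspa1a. Of genes also known from acinar cells, and again chosen after their values were seen, the disulfide isomerase Pdia2 was at -1.50 ± 0.15 and was well above background in the nucleoprotein channel on 1 of the 2 arrays. Serpini2, also an acinar gene and well above background in that channel on 0 arrays, was at least 2.29-fold lower.

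Pdk4, a kinase that blocks entry of pyruvate into the citric acid cycle, was the largest of the 2 liver rises at 1.11 ± 0.27, or 2.15-fold (probe on chromosome 6, 5436327 to 5436386). The other, chosen after its value was seen, was the transcript 3930402G23Rik at 0.60.

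In all, 2 genes were called higher and 52 lower among 16402 measurable liver genes, 0.329% of them. Another 73 genes passed the bounds in opposite directions on the 2 arrays, all with the Cy5 label higher, so gene-specific dye effects were more frequent than calls. Over all measurable genes the 2 arrays correlated at 0.10 (Spearman -0.48), across genes, which are not independent replicates. Counts from a single array were much larger, with 31 higher and 258 lower without replicate 1, and 195 higher and 99 lower without replicate 2. Median centring in place of loess gave 0 higher and 32 lower. With Feature Extraction's deposited log ratios 28 genes were higher and 106 lower, 20.9% higher against 3.70% in the main values.

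**Figure D1:**
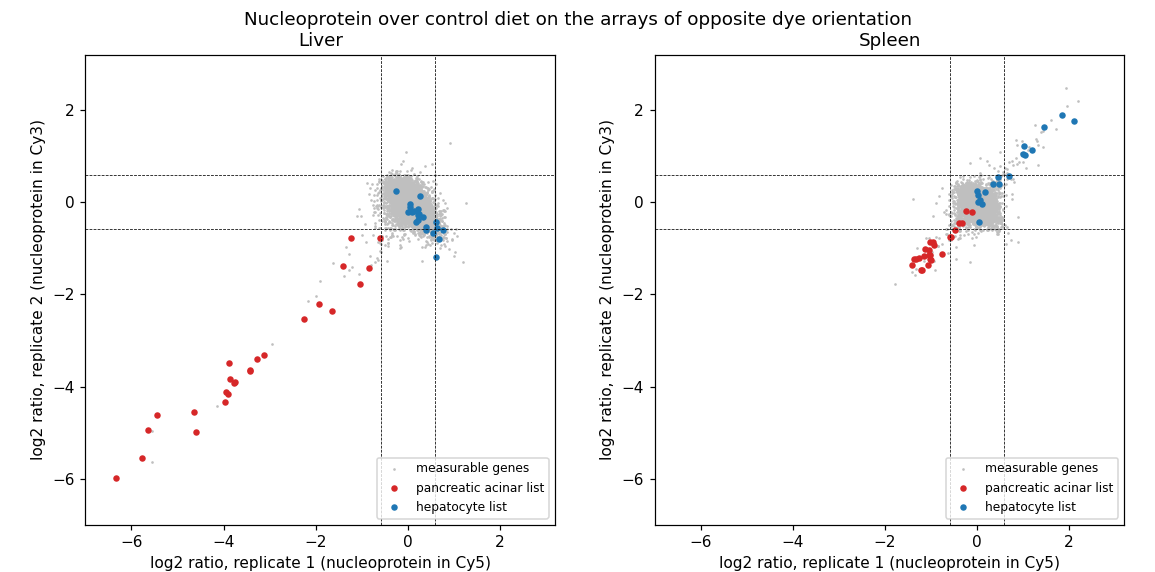
Log2 ratio of nucleoprotein over control on replicate 1 (x axis) against replicate 2 (y axis) for each measurable gene in liver (left) and spleen (right), with acinar genes in red, hepatocyte genes in blue and the 1.5-fold bounds dashed. Acinar genes lie along the diagonal down to -6.33 and -5.98 for Cpb1 in liver, and 17 of 18 hepatocyte genes have a mean ratio above 0 in spleen.

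Lipid synthesis genes were lower in liver as groups, while few single members passed the bounds, and their list medians turned positive with median centring. Of 24 measured genes of cholesterol synthesis and uptake, 23 had ratios below 0, the median was -0.27 (-0.27 and -0.23 on the 2 arrays) and the percentile among random lists was 0. None of these 24 was called. Its members Fdps and Dhcr7, chosen after their values were seen, stood at -0.46 ± 0.05 and -0.46 ± 0.25. The list's brightest members, Ebp at -0.00 ± 0.01 and Tm7sf2 at -0.04 ± 0.14, did not share this shift. Of 34 fatty acid and triglyceride synthesis genes, 25 lay below 0, 2 were called lower and the median was -0.20, again at percentile 0. Fatty acid synthase, Fasn, stood at -0.52 ± 0.06 and the lipogenic regulator Thrsp at -0.65 ± 0.13, both chosen after their values were seen. With median centring in place of loess, which moved the median of all liver genes to 0.17, the medians of these lists were 0.04 and 0.09, below that of all genes. In the same pools the pancreatic acinar list had its median of -3.68 and neutrophil markers one of 0.10.

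Smaller shifts were called in 6 other liver lists besides the acinar list. Neutrophil markers were higher, with 20 of 21 members above 0 and a median of 0.10 (percentile 99.99). S100a9 and Lcn2, the brightest, stood at 0.22 ± 0.45 and -0.07 ± 1.20. Ribosomal protein genes had a median of 0.02. Medians below 0 were found for gluconeogenesis and glycogen genes (-0.11), heat shock and protein folding genes (-0.06), interferon-stimulated genes (-0.05) and purine salvage and breakdown genes (-0.04), and all 4 of these had medians above 0 under median centring, higher than the 0.17 of all liver genes. None of their members except Hspa1a was called. On the single arrays the medians were -0.02 and -0.03 for gluconeogenesis, -0.04 and -0.08 for heat shock, -0.01 and -0.23 for interferon-stimulated, -0.00 and -0.11 for purine salvage and 0.01 and 0.02 for ribosomal protein genes. The lists of the urea cycle (-0.05), amino acid breakdown (-0.04) and male-biased liver genes (-0.06) also lay below percentile 2.5 but had opposite signs on the 2 arrays and were not called.

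No gene of the fixed lists that carry the response to lipopolysaccharide was called in liver. None of 20 measured inflammatory cytokines (median 0.02), 30 chemokines (0.02), 37 Toll-like receptor and NF-kB pathway genes (0.00) or 39 acute phase genes (-0.00) was called. Each of these medians had opposite signs on the 2 arrays, the widest apart being 0.30 and -0.34 for acute phase genes, so small shifts in them could not be resolved. The cytokine Il1b was at 0.26 ± 0.09, Tnf at -0.00 ± 0.30 (chosen after its value was seen) and the chemokine Cxcl10 at 0.14 ± 0.47. De novo purine synthesis genes, the pathway that dietary nucleotides can spare, had a median of -0.02 over 13 members (0.15 and -0.13 on the 2 arrays), with Impdh2 at 0.06 ± 0.01 and Paics at 0.07 ± 0.52. The circadian list had a median of -0.17, at percentile 0, but the 2 arrays gave 0.01 and -0.32, so it was not called. A difference below 1.5-fold in a single gene could not be called here.

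The second comparison asked the same of spleen. Genes of hepatocytes were the main group higher in the nucleoprotein spleen pool. Of 18 measured hepatocyte markers 7 were called higher and 17 lay above 0, with a median of 0.47 (0.46 and 0.48 on the 2 arrays, percentile 100). In the control channel 11 of the 18 were well above background on both arrays. The others were measurable through the nucleoprotein channel, which favours ratios above 0. The fibrinogen chains Fgg at 2.21 ± 0.40, or 4.63-fold (probe on chromosome 3, 83119588 to 83119647), and Fgb at 1.88 ± 0.03, the major urinary proteins Mup1 at 2.20 ± 0.01, Mup3 at 1.70 ± 0.13 and Mup4 at 1.65 ± 0.08, and albumin, Alb, at 1.94 ± 0.24 led the rises. Igfbp1, a liver-secreted binder of insulin-like growth factors, stood at 2.02 ± 0.09, Ahsg at 1.55 ± 0.13, the acute phase gene Saa2 at 2.82-fold, the carboxylesterase Ces1c at 1.47 ± 0.29 and Serpina3k at 1.33 ± 0.06. Mup, Saa and Serpina3 genes belong to families of near-identical copies. Other probes measured 0.72 to 1.28 for Mup1 and 0.37 for Ces1c.

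Of the 39 genes higher in spleen, 34 were at least 8-fold brighter on the liver than on the spleen arrays. The 5 others were Clec2d, a lectin-like ligand of an NK cell receptor, at 1.46 ± 0.09, and, chosen after their values were seen, Ipo7 at 1.07 ± 0.36, Kifc5b at 0.90 ± 0.22, Snrpd3 at 0.79 ± 0.12 and the clone BC021831 at 2.15-fold. Other probes ranged from 0.11 to 0.30 for Ipo7 and from 0.05 to 0.90 for Snrpd3.

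Genes lower in the nucleoprotein spleen pool were mainly those of pancreatic acinar cells and of immunoglobulins. Of 25 measured acinar genes 18 were called lower, all 25 lay below 0 and the median was -1.07 (-1.01 and -1.11). In the nucleoprotein channel 24 of the 25 were still well above background on both spleen arrays. Prss3 was at -1.45 ± 0.07, Try5 at -1.39 ± 0.09, Reg1 at -1.38 ± 0.04, Amy2 at -1.34 ± 0.19, Prss2 at -1.33 ± 0.20, Cpb1 at -1.30 ± 0.11 and Cela3b at -1.29 ± 0.07. Salivary-type amylase, Amy1, was at -1.46 ± 0.17, Reg3b at -1.23 ± 0.03 and Pnlip at -1.21 ± 0.20. The largest single fall among the called spleen genes was that of Dct, a melanin synthesis enzyme of pigment cells, at -1.77 ± 0.00, or 3.42-fold (probe on chromosome 14, 112415582 to 112415642), while its other probe measured -0.52.

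Of the immunoglobulin genes, Igh-1a was lower by -1.22 ± 0.09 and Ighg by -0.71 ± 0.14, while the 2 other probes of Ighg measured -0.58 and 0.02. Over the plasma cell and immunoglobulin list 11 of 13 members lay below 0 and the median was -0.24, although the arrays differed (-0.06 and -0.24). Its brightest members, Igh-VJ558 at 0.21 ± 0.50 and Iglv1 at -0.38 ± 0.43, went opposite ways. Hspa1a was lower by -1.19 ± 0.39 and headed the heat shock list, which had 24 of 32 members below 0 and a median of -0.08. In the same pools the acinar list had its median of -1.07 and hepatocyte markers one of 0.47.

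The counts in spleen were 39 genes higher and 41 lower among 18139 measurable genes, 0.441% of them, against 4 genes past the bounds in opposite directions, all 4 with Cy5 higher. Without the acinar list and the genes at least 8-fold brighter on liver arrays, 5 genes were higher and 23 lower. The 23 still held Prss3, Try5 and Amy1. With a normexp offset of 10 the count of higher genes was 66. Without replicate 2 it was 61, and without replicate 1 the count of lower genes was 88. Median centring gave 30 higher and 10 lower, 75.0% higher against 48.8% in the main values, and Feature Extraction's deposited log ratios gave 102 and 81.

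**Figure D2:**
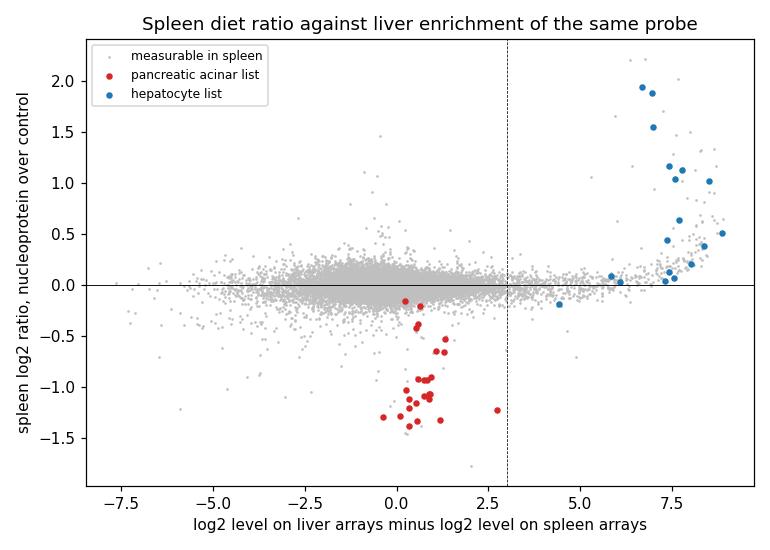
Spleen log2 ratio of nucleoprotein over control (y axis) against the log2 level of the same probe on the liver arrays minus that on the spleen arrays (x axis), for each gene measurable in spleen, with acinar genes in red, hepatocyte genes in blue and the 8-fold bound dashed. Ratios climb above 0 among the probes most enriched on the liver arrays, whose hepatocyte list median is 0.47, and acinar genes lie below 0 at a median of -1.07.

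Lists of liver function moved with the hepatocyte genes in spleen. Acute phase genes had 9 of 34 members called higher and a median of 0.16, male-biased liver genes 4 of 12 and 0.14, coagulation and complement genes 2 of 37 and 0.04, xenobiotic metabolism genes 1 of 34 and 0.03, and bile acid genes 0 of 21 and 0.04. Without genes at least 8-fold brighter on liver arrays, the medians were 0.06 for acute phase, -0.07 for male-biased, -0.02 for coagulation and complement, -0.03 for xenobiotic metabolism and 0.01 for bile acid genes. This removed 11 of the 12 male-biased genes, so -0.07 is the value of Gstp1 alone. Single liver genes were also called in other lists, among them Fbp1 at 1.32 ± 0.02 of the gluconeogenesis list and Fabp1 at 1.17 ± 0.06 of the PPAR alpha list. Glucocorticoid-induced genes, which include Igfbp1, had a median of 0.09 with 16 of 19 members above 0, and 0.07 without the liver-rich genes.

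Cell cycle genes showed the most uniform small shift in spleen. Of 50 measured members 49 lay below 0, with a median of -0.12 (-0.07 and -0.15 on the 2 arrays, percentile 0), and none was called. The brightest, Mcm6 at -0.07 ± 0.55 and Pcna at 0.01 ± 0.28, did not differ beyond the spread of the arrays. Stromal markers (median -0.09), antigen presentation genes (-0.07), platelet markers (-0.06), erythroid markers (-0.06), oxidative stress genes (-0.04) and T cell and NK cell markers (-0.03) also lay below their random lists. Neutrophil markers (0.06, 16 of 22 above 0) and pyrimidine metabolism genes (0.04) lay above, the latter at percentile 95.7 and no longer called without the liver-rich genes. The single arrays gave -0.07 and -0.15 for stromal, -0.02 and -0.08 for antigen presentation, -0.08 and -0.02 for platelet, -0.02 and -0.07 for erythroid, -0.04 and -0.09 for oxidative stress, -0.03 and -0.12 for T cell and NK cell, and 0.00 and 0.04 for pyrimidine genes. None of the members of these 8 lists was called, and they moved in pools whose hepatocyte and acinar medians were 0.47 and -1.07.

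Among the lists of the lipopolysaccharide response in spleen, calls were limited to the acute phase genes, where 9 of 34 were higher. All 9 were at least 8-fold brighter on the liver arrays. Without such liver-rich genes the list median was 0.06, at percentile 98.6. That median was the value of Lcn2, at 0.06 ± 0.25. None of 28 inflammatory cytokines (median 0.00), 29 chemokines (-0.00), 43 interferon-stimulated genes (0.01) or 38 Toll-like receptor and NF-kB pathway genes (0.02) was called, and each of these medians had opposite signs on the 2 arrays. Ifng was at -0.20 ± 0.06, the chemokine Ccl5 at 0.01 ± 0.30, Irf1 at 0.01 ± 0.47 and the NF-kB inhibitor Nfkbia at 0.07 ± 0.21. De novo purine synthesis genes had a median of -0.00 over 13 members.

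**Figure D3:**
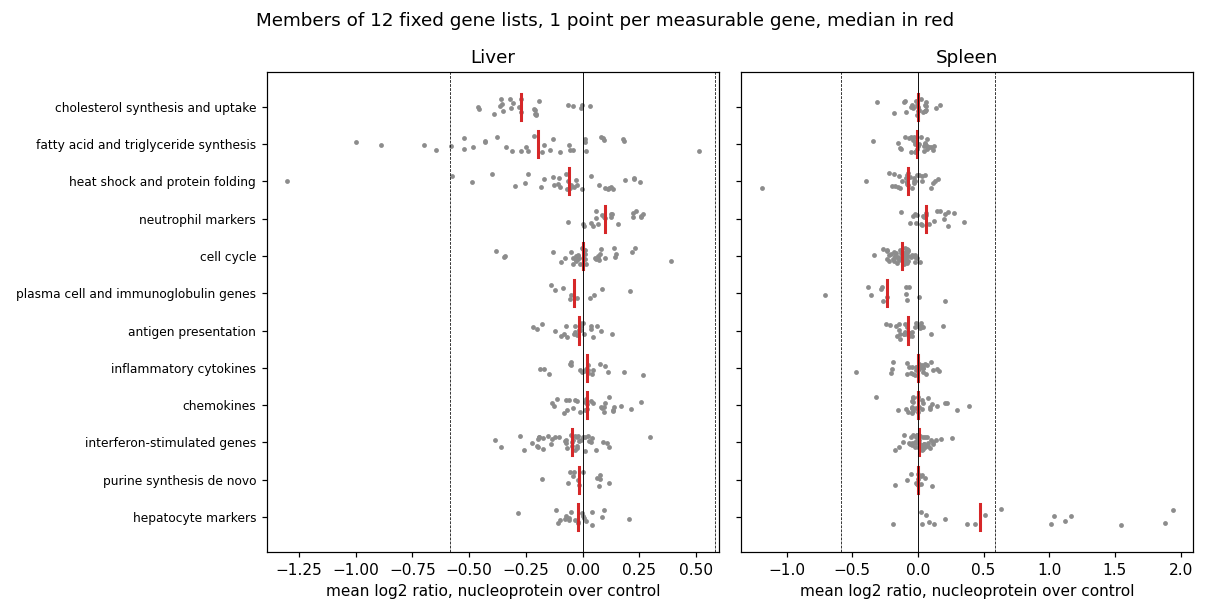
Mean log2 ratio of nucleoprotein over control (x axis) of each measurable member (grey points) of 12 fixed gene lists in liver (left) and spleen (right), with the list median in red and the 1.5-fold bounds dashed. Cholesterol synthesis genes have a median of -0.27 in liver and 0.00 in spleen (0.04 in liver with median centring), cell cycle genes 0.00 and -0.12, and cytokines 0.02 and 0.00.

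In total 28 of 84 list medians were called, 9 in liver and 19 in spleen. In liver 36 of the 42 lists held no called gene, and in spleen 30. Medians of lists that were not called ranged from -0.17 to 0.05 in liver and from -0.04 to 0.03 in spleen.

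The third comparison set the diet ratios of the 2 organs side by side. Genes lower in both organs were mostly acinar genes. Of 51 genes lower in liver and 34 lower in spleen among 15305 genes measurable in both, 25 were shared, against 0.113 for independent lists. The acinar list held 18 of the 25. The other 7 included Hspa1a, at -1.30 ± 0.14 in liver and -1.19 ± 0.39 in spleen (other probes -1.26 to -0.14 and -1.10 to -0.22), the trypsinogens Prss3 and Try5, and, chosen after its values were seen, Dmbt1 at -2.01 ± 0.04 and -0.67 ± 0.01. No gene was higher in both organs (0 shared of 2 and 39), and none was called in opposite directions (0 genes).

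Across the 15305 genes the ratios of the organs correlated at 0.35 (Pearson) and 0.10 (Spearman). Without the acinar list the values were 0.18 and 0.09, and without the liver-rich genes as well 0.24 and 0.10. The genes left still held the digestive enzyme genes Prss3, Try5 and Amy1, called lower in both organs, so the 0.24 is not free of them. The dye part of the ratios, the difference between the 2 orientations, correlated at 0.49 between organs. These are correlations across genes, which are not independent replicates, and no interaction between organ and diet could be tested without replicate pools.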

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

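Of the tests here, those of a shared ratio of acinar signal in both organs and of pancreatic RNA behind the lipid genes were chosen only after the results were seen, as were the reading of islet genes by their distance from background and the checks of the liver-enriched genes with other filters and by the range of their excess. The number of mice per pool is unknown, and diet and pool are confounded throughout.

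Among lists called in at least 1 organ and called genes that the naming rule covers, 3 results went 1 way on each liver array and the opposite way on each spleen array, and the differences were not tested. Acly had a liver minus spleen difference of -0.96 (-0.89 in liver and 0.07 in spleen). The platelet and megakaryocyte list differed by 0.11 (0.05 and -0.06), and the gluconeogenesis and glycogen list by -0.10 (-0.11 and -0.00, with 0.23 in liver under median centring). The last of these rests on single-array medians of -0.02 and -0.03 in liver and 0.02 and 0.01 in spleen, while its median over the mean ratios is below 0 in both organs.

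Acinar genes were lower in the nucleoprotein pools of both organs, by a median of -3.68 in liver. If pancreas had been carried into the control liver pool, islet genes were predicted to fall too, and they did not: 7 measurable islet genes had a median of 0.012 (Ins2 -0.04, Iapp 0.01). That met the bound set beforehand against pancreatic tissue (above -0.2). These genes lay only a median of 0.74 log2 units above the lowest measured signal. Of other acinar genes outside the fixed list, Pdia2 (-1.50) and Serpini2 (at least 2.29-fold) fell. Rbpjl (-0.09), Bhlha15 (-0.11), Nr5a2 (0.05), Gata4 (0.03), Gjb1 (-0.04) and Fkbp11 (-0.12) were not called. Aqp8 (-0.60 ± 0.66) was not called either, but it was 5.75 log2 units brighter on liver than on spleen arrays, so it says little about acinar RNA. Low abundance of the islet genes keeps pancreatic tissue open, and the same median, 0.012, cannot decide on a diet-driven change of acinar genes in liver cells. A change in liver cells alone would leave spleen unchanged, where all 25 list members lay below 0 at a median of -1.07. That argues against liver cells as the only site. Acinar RNA was not confined to the control pools. In the nucleoprotein channel 21 of the 25 genes in liver and 24 in spleen were well above background on both arrays. The excess of control over nucleoprotein signal in spleen was 0.0940 to 0.253 of that in liver for all 25 genes. The highest was 2.69 times the lowest, as a common source of the extra acinar RNA in both control pools could give. A diet effect on RNA of that source is untested.

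Hepatocyte genes were higher in the nucleoprotein spleen pool. Of the 100 genes most enriched on the liver arrays and measurable in spleen, 100% had a ratio above 0 and their median was 0.36, as predicted for liver RNA in that pool. With no filter in spleen 100 of 100 lay above 0 with a median of 0.34, and with the control channel well above background 96 did, with a median of 0.20. Their excess was 0.0146% to 0.818% of their liver signal (median 0.0863%), a 55.8-fold range beyond the 10-fold bound used for acinar genes. Some of the 100 were not well above background in the control channel on both arrays, since that filter changed the set. An excess so near background can vary widely, so the range cannot count against liver RNA in that pool. The prediction set beforehand was met, a single share is not shown, and liver RNA in that pool stays open. Acute phase induction in spleen cells was examined in the 5 acute phase genes that were less than 2-fold brighter on liver arrays (C3, Mt2, Cd14, Socs3 and Il1rn), whose median of 0.10 was too close to its bound of 0.1 to decide, so a diet effect within spleen cells remains open.

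Lipid synthesis genes were lower in liver, except with median centring (list medians 0.041 and 0.085, against 0.17 for all genes). Pancreatic RNA in the control pool would have moved the same 53 genes in spleen to a predicted median of -0.12, and the observed one was -0.0030 with an SD of 0.014. A time-of-day difference between groups was predicted to lower Dbp in spleen as well, where it stood at -0.024 ± 0.16 against -1.47 in liver. That test covers Dbp alone and a shift shared by both organs, so it cannot decide on a shift in liver only. A diet effect on hepatic lipid synthesis may remain as a hypothesis, which pooled RNA without replicate mice cannot test.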

How the results depend on the processing

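The settings without the acinar list, without liver-rich genes and with the dye effect removed were chosen only after the data were seen. No paired analysis was possible because no test was run: replicate numbers name dye orientations, taken here to be of the same pools, which the labels leave open. Leaving out saturated spots moved nothing, as there were 0.

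Gene counts depended on the source of the ratios, on the normalization within arrays and on the use of both arrays. Feature Extraction's deposited log ratios gave 28 genes higher and 106 lower in liver and 102 and 81 in spleen, among them all 2 and 52 of liver, all 39 higher and 40 of the 41 lower of spleen. The authors' series value table gave 28, 106, 102 and 79. Median centring gave 0 higher and 32 lower in liver and 10 lower in spleen. An offset of 10 gave 66 higher in spleen. The 2-fold bound, stricter by construction, gave 0 higher in liver and 21 higher and 18 lower in spleen, and the mean of both arrays gave 4 higher in liver. Leaving out the acinar list left 27 lower in liver, and leaving out liver-rich genes as well left 5 higher and 23 lower in spleen. Prss3, Try5 and Amy1 were still among the lower genes of both organs. With each array left out in turn, liver counts were 31 to 195 higher and 99 to 258 lower, and spleen counts 52 to 61 higher and 59 to 88 lower.

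The correlation of liver with spleen was 0.31 with an offset of 10, 0.25 with Feature Extraction's log ratios and 0.24 with the authors' table. It was 0.30 with no filter on background, 0.24 without the acinar list and liver-rich genes, and 0.38 to 0.42 with each array left out. Without the acinar list and liver-rich genes, the genes left still held Prss3, Try5 and Amy1.

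Of the called list medians, 10 values changed sign, 95 moved by more than the spread of the arrays and 249 did not. With median centring, liver medians were 0.30 for interferon-stimulated, 0.21 for purine salvage, 0.23 for gluconeogenesis, 0.041 for cholesterol, 0.085 for fatty acid and 0.33 for heat shock genes. In spleen, xenobiotic metabolism was at -0.0086 when both channels had to be well above background. Without liver-rich genes it was at -0.027, male-biased liver genes at -0.072 (Gstp1 alone) and coagulation and complement at -0.018. Called genes among those named changed sign in 0 cases, and of all values of named genes 220 moved by more than the spread of the arrays and 2204 did not. Apart from settings stricter by construction or that leave genes out, the cause was not tested. Signal over background limits the range of small folds among dim probes.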

Other observations

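Immunoglobulin probes were lower in the nucleoprotein spleen pool well beyond the fixed list. The immunoglobulin grouping and the clock and lipid genes named here were chosen only after their values were seen. All genes whose description in the files names an immunoglobulin or antibody chain were pooled. Of 89 measurable in spleen, 72 lay below 0 and 8 were called lower, with a median of -0.30 (-0.26 and -0.32 on the 2 arrays), outside the range of -0.02 to 0.02 that held 95% of matched random lists. In liver 22 were measurable and 1 was called lower, with a median of -0.03 (-0.01 and -0.02 on the 2 arrays), below the random range of -0.02 to 0.04. A group of 6 calls lay within chromosome 6, 70233777 to 70690280, around the probe of the kappa variable gene Igkv3-12, at -1.10 ± 0.25. Variable region probes are similar in sequence, so these calls are not independent.

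In liver, besides Dbp, the clock output genes Tef, Per2 and Ciart stood at -0.45 ± 0.14, -0.53 ± 0.25 and -0.70 ± 0.37, and Arntl, which peaks at the opposite time of day, at 0.40 ± 0.60. Other probes measured -0.15 to -0.11 for Tef and -0.04 for Per2. The clock list itself was not called in liver, and its brightest members Nfil3 and Bhlhe40 stood at 0.36 ± 0.03 and 0.10 ± 0.29. As that list holds Arntl beside Dbp, its median mixes genes that peak at opposite times and cannot register a shift of phase. In spleen Tef, Per2, Ciart and Arntl stood at 0.05 ± 0.04, 0.01 ± 0.28, 0.09 ± 0.14 and 0.02 ± 0.10. The transcript described in the files as glycerol-3-phosphate acyltransferase, M77003, which starts glycerolipid synthesis, was called lower in liver at -0.85 ± 0.20. Slc37a4, the glucose-6-phosphate transporter, stood at -0.70 ± 0.33.

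More melanocytes in the control spleen pool were tested as a hypothesis for Dct. The 5 other measurable melanocyte genes had a median of -0.17, with Mlana at -0.48 ± 0.17 and Pmel at -0.34 ± 0.11 and 4 of 5 below 0, too close to the bound of -0.2 set beforehand to decide. For Clec2d, Ipo7, Kifc5b, Snrpd3 and Cyp20a1, a genetic difference between the mice of the pools was predicted to give the same change in liver. Their median in liver, turned to the spleen direction, was 0.071, which met the bound set beforehand against a genetic difference. The SD of 0.46 between the arrays was wider than this median, so the question is left undecided.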
